A study of Mus musculus with 31 samples.

How the data were processed

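Livers of Ames dwarf and wild-type mice of 4, 10 and 22 months were profiled on Affymetrix arrays, 1 array per animal by the names in the labels, with 15 dwarf and 16 wild-type arrays in 6 groups of 5 or 6. The deposited values are MAS5 signal, an intensity on a linear scale, per the submitters' processing notes. The version and target of MAS5 are not given in the sources used here. The 2% trimmed mean of an array ran from 494.6 to 496, and each array was scaled to 500, by factors of 1.008 to 1.011. Groups were taken from the labels. The labels give no batch, sex or time of day. A free-text field of the labels names a fly tissue, while the organism, source and title fields name mouse liver, and the mouse fields were used. Of the pairs of arrays, 0 held identical values. Column names were matched to sample titles, and 0 value columns were left unused.

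Of 45037 probe sets, 34945 carried 1 gene symbol, 932 carried several and 9160 were not named here. A probe set was tested when its signal was above the 40th percentile of its own array on at least 5 arrays, which 33908 passed, 27302 of them with 1 symbol. The probe set with the highest mean log2 signal stood for its gene, giving 15421 genes. Values were taken as log2 of signal plus 16. Differences on this scale understate those of genes with low signal. A log2 difference is dwarf minus wild type, or the older minus the younger age. In R 4.3.3, limma 3.58.1 was fitted to the 6 group means with a mean-variance trend. Its adjusted p is by Benjamini-Hochberg over all genes, with a threshold of 0.05. The comparison over all ages is the mean of the 3 age-specific differences. The interaction is the change from 4 to 22 months in dwarf minus that in wild type, and an F-test covered both interaction terms. No paired analysis was possible because the animals of the groups differ. The direction of an array was read against the mean of the group it was compared with. For the interaction, arrays of dwarf at 22 months were read against the dwarf mean at 4 months plus the wild-type change.

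Of 36 gene lists with 606 members, 534 had a named probe set and 516 were tested. Lists with at least 5 members tested, 34 of them, were tested by camera with a preset correlation of 0.01, adjusted over the lists within a comparison. Camera compares a list with all other genes, and was repeated with an estimated correlation and on ranks. Fry, which asks whether a list's genes move one way on balance, was run as well. The test of wild-type ageing genes at 10 months, and that of the mean signed difference, permuted array labels exactly and two-sided.

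The genes, lists, groups, tests of the comparisons and most alternatives were fixed before the data were examined. One further item of the rule is not reported here. The genes named are, first, the 12 largest rises and 12 largest falls over all ages with the same sign at all 3 ages. To these come the 6 largest rises and falls at each age and for each change from 4 to 22 months, the 8 genes with the smallest adjusted p for the interaction and for the F-test, list members, and control genes of the X and Y chromosome. Xist was read on 1 of its probe sets, not the one with the highest mean signal. The Y-linked gene Ddx3y and the array's control probe sets were not tested here. Alternatives tried were quantile normalization, median centring, the deposited values unscaled, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile. Others were each probe set on its own, the mean of a gene's probe sets, array weights, no trend, robust variances and a fit of only the compared groups. Each array was also left out in turn. For the wild-type ageing genes, the 200 risers and 200 fallers with the smallest p were tried. Chosen after seeing the data were leaving out the 4 arrays with Xist above 1000, a clock covariate and leaving single arrays out of the choice of wild-type ageing genes. The test of the mean signed difference, random gene lists matched on signal and random splits of the arrays were not among the tests fixed beforehand. Of the 48 genes named over all comparisons by rank, 12 had 15 other probe sets, compared 26 times over the comparisons that named the gene. In 1 of these the sign was opposite, not past the threshold.

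Tested on simulated data, with 50 genes shifted by each of 0.5, 1, 2 and 4 log2, the comparison at 4 months recovered 16%, 58%, 90% and 100% of them, that over all ages 56%, 84%, 100% and 100%, and the interaction 4%, 38%, 74% and 90%. False calls were 5 of 137, 8 of 178 and 6 of 109. The simulated genes and arrays were independent, so these rates leave out correlation between genes and arrays that stand apart.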

Results

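Liver RNA of Ames dwarf mice, which are short of growth hormone, prolactin and thyroid-stimulating hormone, was compared with liver RNA of wild-type mice at 4, 10 and 22 months of age. The series title calls the mutant long-lived. There were 31 arrays, 1 per animal by the animal names in the labels: 5 in each group, except 6 for wild type at 22 months. Signal was measured for 45037 probe sets, and 15421 genes were tested. The median signal of an array ran from 168.1 to 227.2, and the correlation between any pair of arrays, across probe sets, from 0.8734 to 0.9397. The first principal component held 15.26% of the variance and the second 7.429%. The number of arrays per group limits the precision of every value. The labels gave no sex, batch or time of day. On 4 arrays the signal of Xist, a transcript of the inactive X chromosome, was above 1000: dwarf 10 months replicates 1 and 4, dwarf 22 months replicate 1 and wild type 22 months replicate 2. On the other arrays it was at most 131.7, and the signal of the Y-linked gene Eif2s3y there ran from 588.1 to 1264. All arrays stayed in the comparisons, and where leaving out these 4 ended the call of a list or of a gene named by rank the value is given.

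**Figure D1:**
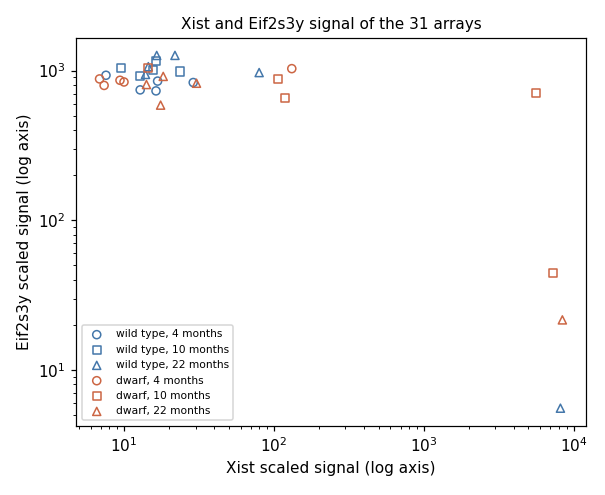
Signal of Xist (x axis, log scale) against signal of the Y-linked gene Eif2s3y (y axis, log scale), 1 point for each of the 31 arrays. Of the 4 arrays with Xist above 1000, dwarf 10 months replicate 1 also had Eif2s3y at 707.8, and the others had 44.28, 21.6 and 5.551.

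The first comparison asked which liver transcripts differed between dwarf and wild type when the 3 ages were given equal weight. Igf1, the growth factor that the liver secretes under growth hormone, differed by -2.59 log2 (SE 0.15, adjusted p = 1.22e-14), and Igfals, the subunit that keeps it in the circulation, by -2.54 (adjusted p = 1.2e-15). Both were below the wild-type mean on 15 of 15 dwarf arrays. At 4 months the Igf1 signal was 2011 ± 471 in dwarf (SD, n = 5) and 18220 ± 2704 in wild type (SD, n = 5). The IGF-binding proteins Igfbp1 (4.32, adjusted p = 7.52e-10) and Igfbp2 (1.58, adjusted p = 6.58e-08, 14 of 15 arrays) went the other way. Igfbp3 and Igfbp4, also on the list, did not pass. Downstream of the growth hormone receptor, the feedback inhibitor Cish (-0.80, adjusted p = 0.00602), the transcription factor Stat5a (-0.52) and the kinase Jak2 (-0.51) fell, and the receptors Igf1r (0.29) and Igf2r (0.37) rose. The receptor gene Ghr (-0.15, adjusted p = 0.117) and Socs2 (-0.06, adjusted p = 0.795), another feedback inhibitor, did not pass. Of the 15 members of the growth hormone and IGF-1 list, 4 were higher and 5 lower over all genes, and 4 higher and 6 lower adjusted over the list alone. The list as a whole, whose members go both ways by function, did not pass (camera adjusted p = 0.152), while its genes moved on balance one way by fry (adjusted p = 5.45e-06).

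The largest rise in dwarf livers was that of Sult2a2, a female-biased sulfotransferase of steroids and bile acids, at 8.26 log2 (SE 0.58, adjusted p = 6.96e-13). At 4 months its signal was 23840 ± 4693 in dwarf and 49 ± 38 in wild type (SD, n = 5 each). Behind it came the fatty acid hydroxylase Cyp4a14 (5.87), the female-biased P450 Cyp2b13 (5.62), the trypsin inhibitor Spink1 (5.09), the estrogen sulfotransferase Sult1e1 (4.60), the hydroxy acid oxidase Hao2 (4.52) and Igfbp1. Then followed the metal-binding Mt1 (3.64), the keratin Krt23 (3.57), the desaturase Scd2 (3.57), the P450 Cyp2b9 (3.56) and the transporter-family gene Slc16a5 (3.45). The largest fall was that of Hsd3b5, a male-biased steroid-metabolising enzyme, at -7.61 (SE 0.58, adjusted p = 4.35e-12). It was followed by the urinary pheromone carrier Mup10 (-6.78, adjusted p = 4.1e-21), the organic anion transporter Slco1a1 (-6.06), the serpin pseudogene Serpina4-ps1 (-5.43), the elongase Elovl3 (-5.27) and Dio1 (-4.87), the deiodinase that makes active thyroid hormone. The list ended with the secreted protein gene Wfdc21 (-4.80), the oxysterol hydroxylase Cyp7b1 (-4.21), the adipokine Serpina12 (-3.72), the taurine-synthesis enzyme Csad (-3.66), Mup5 (-3.46) and the male-biased hydroxylase Cyp4a12a (-3.43). Each of these 24 genes lay on its side of the wild-type mean on all 15 dwarf arrays. In all, 2945 genes passed by limma, 1671 higher and 1274 lower, or 19.1% of those tested, and 181 and 164 of them changed 2-fold or more. The Cyp2b, Sult2a, Mup and serpin genes have close relatives whose transcripts probes can share, so the values stand for the probe set. The log2 sizes, and so the order, depend on the pseudocount where 1 group lies near the floor. The mean Hsd3b5 signal in dwarf was 9.41 to 15.1, with an array's 10th percentile at 18.1 to 27.5. With pseudocounts of 1 and 64 the values were -8.69 and -6.27 for Hsd3b5, dwarf minus wild type over all ages, and 8.83 and 7.34 for Sult2a2, dwarf minus wild type over all ages. A second probe set did not pass for Mt1 (0.69, adjusted p = 0.15) and Slc16a5 (-0.01, adjusted p = 0.988). Further probe sets gave smaller changes in the same direction, past the threshold, for Scd2 (2.86 and 1.41), Cyp7b1 (-3.69 and -1.16) and Slco1a1 (-4.69).

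**Figure D2:**
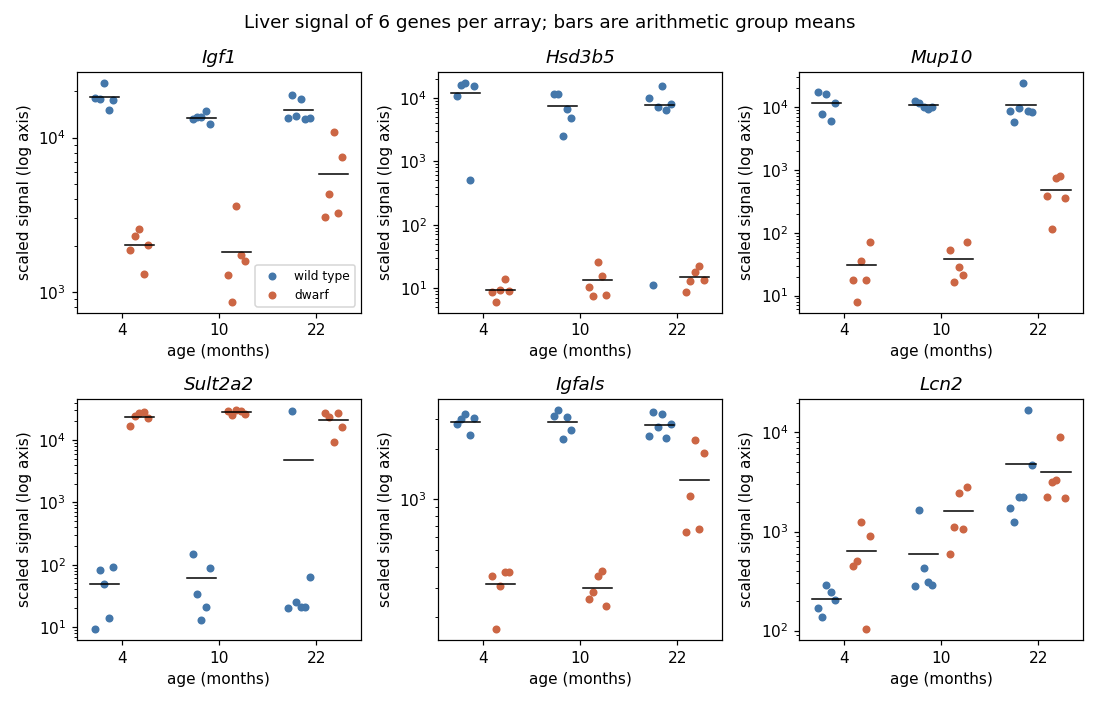
Signal (y axis, log scale, array units) of Igf1, Hsd3b5, Mup10, Sult2a2, Igfals and Lcn2 for each array, by genotype and age in months, with bars at the arithmetic mean of each group. The Igf1 mean in dwarf went from 2011 at 4 months to 5776 at 22 months, and 1 wild-type array of 22 months had Sult2a2 at 29000.

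Among the 34 gene lists tested, the sex-biased liver genes moved farthest. Of 17 male-biased genes that depend on growth hormone, 16 were lower (16 adjusted over the list alone), with a median of -2.66 (camera adjusted p = 3.3e-36, and 0.000277 with an estimated correlation). They included Hsd3b5, Mup3 (-3.39), Keg1 (-3.21), Nudt7 (-2.66), the growth factor receptor Egfr (-1.30), Cyp2d9 (-1.13) and the complement gene C6 (-1.11). Of 14 female-biased genes, 11 were higher (11 adjusted over the list alone), with a median of 2.10 (adjusted p = 1.58e-15, and 0.0122 with an estimated correlation). Beside Sult2a2 and Cyp2b13 these were genes such as the lipoprotein receptor Vldlr (2.79), the thioesterase Acot3 (2.37), Fmo2 (2.32) and the steroid hydroxylase Cyp17a1 (1.24). Thyroid hormone-responsive genes were lower over all ages, with a median of -0.38 (adjusted p = 8.88e-05, and 0.0425 with an estimated correlation), but their median was -0.55 at 4 months, -0.29 at 10 months and -0.06 at 22 months. Dio1, the malic enzyme Me1 (-2.26), the glycerol phosphate shuttle enzyme Gpd2 (-1.10), Bcl3 (-1.03) and Klf9 (-0.47) fell, and the thyroid hormone transporter Slc16a10 rose (0.51). That made 5 lower and 1 higher, or 6 and 1 adjusted over the list alone, and Thrsp did not pass (-0.67, adjusted p = 0.0938).

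Enzymes that clear foreign compounds were higher as well. Xenobiotic monooxygenases had a median of 0.57 (adjusted p = 3.79e-12, and 0.0122 with an estimated correlation), with 13 of 21 higher and 16 adjusted over the list alone. Among them were Cyp2c37 (2.04), Cyp2b10 (1.87), Cyp2c38 (1.25), Fmo4 (1.002) and the nuclear receptors Nr1i3 (0.57) and Nr1i2 (0.48), while Cyp2b13, Cyp2b9, Cyp2b10 and Fmo2 are also on the female-biased list. Glutathione and NRF2 targets had a median of 0.27 (adjusted p = 1.74e-06, and 0.106 with an estimated correlation). The transferases Gsta2 (1.67), Gsta4 (1.37) and Gstm3 (1.33) and the quinone reductase Nqo1 (1.20) rose, and Gclm (-0.62), a subunit of the enzyme that starts glutathione synthesis, and Ephx1 (-0.40) fell. In this list 13 were higher and 2 lower, and 14 and 2 adjusted over the list alone.

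Lists of fuel metabolism had medians smaller in size than those of the sex-biased lists, a contrast that was not tested itself. Gluconeogenesis genes had a median of 0.24 (camera adjusted p = 0.00282, and 0.248 with an estimated correlation): the coactivator Ppargc1a (1.51), Got1 (0.89), Pck1 (0.69) and Gpt (0.60) were among the 6 of 12 that rose, and G6pc (-0.01) did not. Adjusted over the list alone, 6 were higher and 1 lower. Urea cycle genes had a median of 0.23 (adjusted p = 0.00546, and 0.208 with an estimated correlation), with 6 of 8 higher (7 adjusted over the list alone), among them Slc25a13 (0.59), Asl (0.32), Otc (0.26) and Cps1 (0.22). Oxidative phosphorylation genes had a median of 0.12 (adjusted p = 0.000165, and 0.513 with an estimated correlation), with 12 of 38 higher and 1 lower (14 and 2 adjusted over the list alone). Ndufa5 (0.55), Ndufa2 (0.46) and Sdhc (0.43) led the risers. Fatty acid synthesis genes had a median of -0.19 (adjusted p = 0.0183, and 0.548 with an estimated correlation), where Me1 and Elovl5 (-0.26) fell and 1 passed adjusted over the list alone. Without wild type 4 months replicate 4 that call ended (0.0561), as it did without the 4 high-Xist arrays (0.101). Unfolded protein response genes were lower, with a median of -0.30 (adjusted p = 0.000574, and 0.163 with an estimated correlation). Sdf2l1 (-1.14), the chaperones Hspa5 (-0.55) and Calr (-0.47), Dnajb9 (-0.48) and Xbp1 (-0.36) fell, and Trib3, a pseudokinase induced in that response, rose (0.98, 12 of 15 arrays). The list had 6 lower and 1 higher of 13, and 8 and 1 adjusted over the list alone.

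Markers of other liver cells and of dividing cells were slightly higher in dwarf, and none of these calls held with an estimated correlation. The MHC class II genes H2-Aa (0.92), H2-Ab1 (0.44) and Cd74 (0.40) rose, for a list median of 0.36 (camera adjusted p = 0.0205, and 0.285 with an estimated correlation). Endothelial markers had a median of 0.29 (0.016, and 0.285 with an estimated correlation), with Fcgr2b (0.55), Stab2 (0.39) and Clec4g (0.32) higher. Stellate cell and matrix markers had a median of 0.29 (0.0205, and 0.302 with an estimated correlation), with Sparc (0.56), Dcn (0.52), Col4a1 (0.43) and Col1a2 (0.33) higher, and lost the call without the 4 high-Xist arrays (0.126). Proliferation genes had a median of 0.28 (0.0205, and 0.302 with an estimated correlation), or 0.40, 0.57 and 0.03 at 4, 10 and 22 months, with Birc5 (1.05), Mcm6 (1.03) and Pcna (0.62) among the 8 of 19 that rose. The counts over all genes were 3 of 6, 3 of 10, 4 of 14 and 8 of 19, all higher. Adjusted over the list alone they were 3, 6, 6 and 8 higher, with 1 proliferation gene lower. The acute phase list did not pass (0.65): Cd14 (1.02) and Lcn2 (0.98) rose while Saa4 (-1.12), Apcs (-0.78) and Orm1 (-0.67) fell. The Kupffer cell list did not pass either (0.391), and in the B cell list the immunoglobulin gene Ighm fell (-1.58, adjusted p = 1.18e-06). In all, 14 of 34 lists passed, 10 higher and 4 lower, and 4 of these held with an estimated correlation. At 22 months the median was also near 0 for endothelial markers (0.06), oxidative phosphorylation (0.07) and fatty acid synthesis (0.01).

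**Figure D3:**
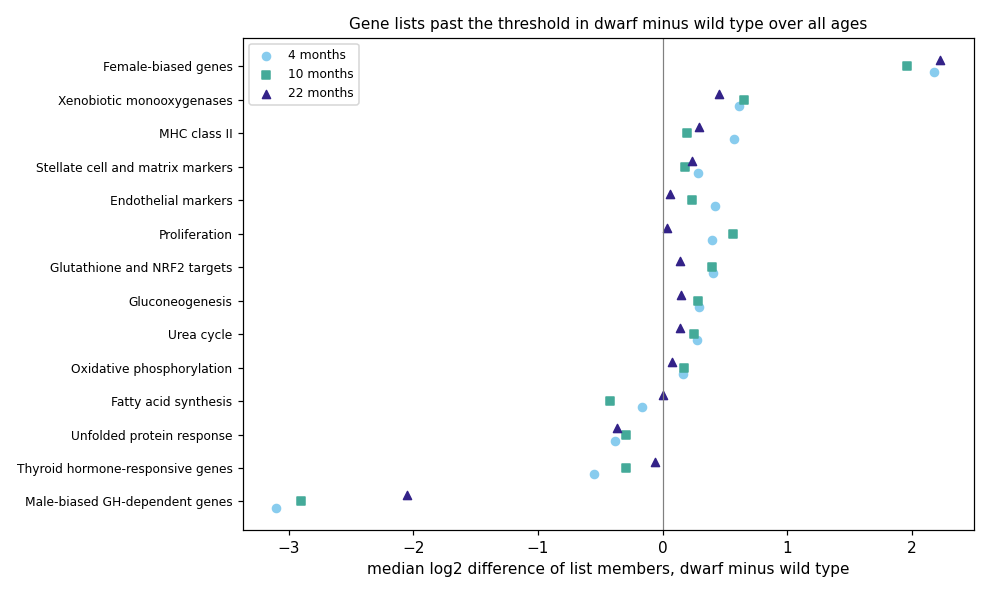
Median log2 difference, dwarf minus wild type (x axis), at 4, 10 and 22 months for the 14 lists that passed over all ages (y axis), 1 point per list and age. The male-biased list, with -2.66 over all ages, and the female-biased list, with 2.10, lie farthest from 0.

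The same question was asked at each age alone. At 4 months Sult2a2 (8.73), Cyp2b13 (6.27), Cyp4a14 (6.19), Sult1e1 (5.91), Spink1 (5.52) and Igfbp1 (5.07) rose most, and Hsd3b5 (-8.21), Mup10 (-8.05), Elovl3 (-6.59), Slco1a1 (-6.54), Wfdc21 (-6.24) and Serpina4-ps1 (-5.85) fell most. At 10 months Sult2a2 (8.83), Cyp4a14 (6.36), Cyp2b13 (5.82), Spink1 (5.57), Igfbp1 (5.46) and Hao2 (5.14) led the rises, and Hsd3b5 (-7.81), Mup10 (-7.73), Wfdc21 (-6.09), Serpina4-ps1 (-5.93), Slco1a1 (-5.76) and Dio1 (-4.92) the falls. At 22 months the leaders were Sult2a2 (7.23), Cyp4a14 (5.07), Cyp2b13 (4.78), Spink1 (4.19), the leucine-rich repeat gene Lrtm2 (3.78) and Hao2 (3.75) among rises. Hsd3b5 (-6.80), Slco1a1 (-5.87), Elovl3 (-4.58), Mup10 (-4.55), Serpina4-ps1 (-4.51) and Cyp7b1 (-4.05) led the falls. Several of these sizes depended on 1 array. Without wild type 22 months replicate 2, Sult2a2 was at 8.79, Cyp2b13 at 5.73, Hao2 at 4.58, Hsd3b5 at -8.19, Elovl3 at -5.36 and Serpina4-ps1 at -5.13 at 22 months. Without wild type 4 months replicate 4, Igfbp1 was at 5.84 and Hsd3b5 at -9.18 at 4 months, and Wfdc21 at 10 months was at -5.43 and -6.76 without dwarf 10 months replicates 2 and 5. All 12 genes named at an age lay on their side of the wild-type mean on all 5 dwarf arrays of that age. The count of genes past the threshold by limma was 1538 at 4 months (862 higher, 676 lower), 955 at 10 months (514 and 441) and 635 at 22 months (379 and 256). With median centring the balance turned at 4 months (574 higher, 640 lower) and 10 months (333 and 375), and at 22 months it was 409 and 155.

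The count at 22 months depended on single arrays. It was 398 without dwarf 22 months replicate 1, 1041 without wild type 22 months replicate 2, 376 without replicate 4 and 385 without replicate 5. Between 4 and 10 months 321 higher and 295 lower genes were shared, where independence would give 28.7 and 19.3. Between 4 and 22 months 195 and 152 were shared (expected 21.2 and 11.2), and between 10 and 22 months 171 and 143 (expected 12.6 and 7.32). No array was used at more than 1 age, but all ages shared the fit's variance for each gene. That can raise sharing above the counts given by independence. Of the 2115 genes that passed at any age, 141 were higher and 124 lower at all 3. The orphan receptor gene Gpr37 was the 1 gene that passed in opposite directions, higher at 4 months (1.87) and lower at 22 months (-1.73).

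How the wild-type liver changed from 4 to 22 months was asked next. The iron-siderophore binder Lcn2, an acute phase gene, rose by 3.82 log2 (SE 0.56, adjusted p = 0.000164). The estrogen sulfotransferase Sult1e1 (3.66), the neutrophil protease inhibitor Serpinb1a (3.50, adjusted p = 1.59e-05), Gpr37 (2.96), the muscle protein gene Neb (2.39) and the NF-kB adaptor Tifa (2.14) rose next. The falls were led by Gm12130 (-2.45), the acetyltransferase-family gene Nat8f5 (-2.26), Csad (-2.12, adjusted p = 5.26e-05), Nkain4 (-2.09), 1110028F11Rik (-1.97) and Dio1 (-1.94). Of these 12 genes, 11 lay on their side of the 4-month mean on all 6 arrays of 22 months, and Dio1 on 5 of 6. A second probe set of Serpinb1a rose by less (1.48). Among list members with known roles, immunoglobulin Igha (2.06) and its joining chain Jchain (1.84), the metallothionein Mt2 (1.76) and the calcium-binding S100a9 (1.65) rose. Me1 fell by 1.502 log2 (6 of 6 arrays), as did the superoxide dismutase Sod1 (-0.82) and the glutathione synthesis genes Gclc (-0.81) and Gclm (-0.73). By limma 614 genes passed, 296 higher and 318 lower. With median centring, which put the median of all genes at -0.15 where it had been 0.02, 158 were higher and 992 lower.

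Several of those calls rested on single arrays. The count was 324 without wild type 22 months replicate 3, 246 without replicate 5, 291 without replicate 6 and 325 without wild type 4 months replicate 1. Wild type 22 months replicates 3 to 6 stood apart from all other arrays on the second principal component. Neb did not pass without wild type 22 months replicates 3 (0.0916), 4 (0.068), 5 (0.0815) or 6 (0.0513), and without wild type 4 months replicates 1 (0.0753), 2 (0.0567), 3 (0.0638) or 4 (0.0661). Dio1 did not pass without wild type 22 months replicates 3 (0.0982), 5 (0.0565) or 6 (0.0875) and without wild type 4 months replicates 1 (0.0963), 3 (0.0707) or 4 (0.0796), and Nat8f5 without wild type 4 months replicates 4 (0.0601) or 5 (0.0524).

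In ageing wild-type livers the respiratory chain list moved toward lower values. Oxidative phosphorylation genes had a median of -0.30 (camera adjusted p = 1.43e-17, and 0.292 with an estimated correlation), with Ndufb3 (-0.62), Sdhc (-0.50), Atp5d (-0.47), Ndufa1 (-0.47) and Sdha (-0.42) among the 11 of 38 that were lower (23 adjusted over the list alone). With quantile normalization the median was -0.17. Fatty acid oxidation genes had a median of -0.33, or -0.22 with quantile normalization (3.83e-07, and 0.292 with an estimated correlation), with the thiolase Acaa1b (-0.85), the carnitine carrier Slc25a20 (-0.63) and Decr1 (-0.55) lower, 4 of 24 in all and 8 adjusted over the list alone. Acute phase and macrophage lists moved toward higher values, while interferon-stimulated genes did not pass (median -0.15, adjusted p = 0.501). Acute phase genes had a median of 0.51 (4.48e-06, and 0.292 with an estimated correlation), with Lcn2, Orm2 (1.99), Apcs (1.21), Saa3 (1.004) and Lbp (0.62) among 7 of 20 higher (10 adjusted over the list alone), and Saa1 not past the threshold (1.94, adjusted p = 0.107). Kupffer cell and macrophage markers had a median of 0.47 (3.56e-06, and 0.292 with an estimated correlation), with Ccl6 (1.19), C1qa (1.18), Lyz2 (1.11) and Mpeg1 (0.80) higher, 4 of 15 and 7 adjusted over the list alone. Proteasome genes had a median of -0.19 (0.000438, and 0.505 with an estimated correlation), where Psmb7 fell (-0.40) and Psmc1 rose (0.40). Adjusted over the list alone 6 were lower and 1 higher, and with quantile normalization the list did not pass (0.428). None of these 5 lists lost its call when any single array was left out.

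The other 7 lists were called in wild type with less margin, and 6 of them lost the call with quantile normalization. B and plasma cell markers were higher, with Igha and Jchain the 2 of 11 past the threshold by both counts (median 0.38, adjusted p = 0.0208, and 0.401 with an estimated correlation), and did not pass without wild type 22 months replicate 1 (0.0636) or wild type 4 months replicate 2 (0.0509). The male-biased list was lower with 0 of 17 members past the threshold by either count (median -0.31, adjusted p = 0.0208, and 0.632 with an estimated correlation). The female-biased list was higher, with Cyp3a44 (1.83) the 1 of 14 past the threshold by both counts (median 0.57, adjusted p = 0.0477, and 0.657 with an estimated correlation). Fatty acid synthesis was lower, with Me1 the 1 of 16 past the threshold by both counts (median -0.28, adjusted p = 0.0218, and 0.657 with an estimated correlation), and so were bile acid genes, with the receptor Nr1h4 (-0.55) the 1 of 14 past it and 2 adjusted over the list alone (median -0.13, adjusted p = 0.0266, and 0.292 with an estimated correlation). Antioxidant genes had a median of -0.20 but a mean of 0.03, as Sod1 and Glrx (-0.45) fell and Mt2 rose (adjusted p = 0.0266, and 0.433 with an estimated correlation), with 7 lower and 2 higher adjusted over the list alone. Glycolysis genes had 0 of 6 past the threshold and 2 lower adjusted over the list alone (median -0.22, adjusted p = 0.0266, and 0.292 with an estimated correlation). With quantile normalization the values were 0.242 for the male-biased list, 0.141 female-biased, 0.442 fatty acid synthesis, 0.696 bile acid, 0.676 antioxidant and 0.506 glycolysis. In all 12 lists passed, 4 higher and 8 lower, none with an estimated correlation, and with quantile normalization 5 were higher and 2 lower.

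Those 6 lists also depended on single arrays. The male-biased list did not pass without wild type 22 months replicate 2 (0.46), 1 of the 4 high-Xist arrays, without all 4 (0.414) or without wild type 4 months replicate 2 (0.0509). The female-biased list did not pass without wild type 22 months replicate 2 (0.842), all 4 high-Xist arrays (0.831) or wild type 4 months replicates 2 (0.165), 3 (0.0605) or 5 (0.167). Fatty acid synthesis did not pass without wild type 22 months replicate 3 (0.0804) or wild type 4 months replicate 4 (0.288). Bile acid genes did not pass without wild type 22 months replicates 1 (0.0574) or 5 (0.0983) or wild type 4 months replicates 2 (0.0581), 3 (0.0558) or 5 (0.0611). Antioxidant genes did not pass without wild type 22 months replicate 1 (0.188) or wild type 4 months replicate 2 (0.0581), and glycolysis not without wild type 22 months replicate 1 (0.0727) or wild type 4 months replicates 1 (0.0501) or 4 (0.121).

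In dwarf livers Mup10, which is on no list here, and a few members of the growth hormone and male-biased lists rose from 4 to 22 months. Mup10 rose by 3.32 log2 (SE 0.40, adjusted p = 1.95e-05), Igfals by 1.85 (adjusted p = 4.33e-05), Igf1 by 1.37 (adjusted p = 0.00685) and Mup5 by 1.39 (adjusted p = 0.0395), each above the 4-month mean on 5 of 5 arrays. Neither of the 2 lists passed. The growth hormone and IGF-1 list had 2 of 15 higher (camera adjusted p = 0.794), and the male-biased list had 1 of 17 higher and 1 lower (adjusted p = 0.0951). The Igfals signal was 316 ± 86 at 4 months and 1302 ± 733 at 22 months in dwarf (SD, n = 5 each), against 2779 ± 403 in wild type at 22 months (SD, n = 6). In dwarf at 22 months the Igf1 signal was 10820 and 7468 on replicates 3 and 5. It was 3049, 4293 and 3250 on replicates 1, 2 and 4. Replicates 3 and 5 were also the highest of that group for Igfals. The largest rises were those of Wfdc21 (4.19, or 5.03 without dwarf 22 months replicate 1), Mup10, Lcn2 (2.75, adjusted p = 0.0111), the acetyltransferase-family gene Nat8 (2.58), Tifa (2.21) and the olfactomedin Olfm3 (2.13). The largest falls were those of the lipoprotein lipase Lpl (-2.43, adjusted p = 0.000687), the ribonuclease P subunit Rpp21 (-2.29, adjusted p = 0.00061), the adipogenic receptor Pparg (-2.13), Bhlhb9 (-1.80), Fgd1 (-1.69) and the protamine gene Prm3 (-1.69). All 12 lay on their side of the 4-month mean on 5 of 5 arrays. The interferon-induced GTPase Iigp1 (0.78) and the cholesterol synthesis enzyme Sqle (1.10) rose as well. By limma 185 genes passed, 87 higher and 98 lower, or 95 and 42 with quantile normalization.

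That count was 66 without dwarf 22 months replicate 3, 78 without replicate 4, 101 without dwarf 4 months replicate 2 and 89 without replicate 5. Prm3 did not pass without dwarf 22 months replicates 1 (0.0692), 2 (0.078), 3 (0.0788) or 4 (0.091) or dwarf 4 months replicates 1 (0.0898), 2 (0.123), 4 (0.0666) or 5 (0.0817), nor without the 4 high-Xist arrays (0.0782). Fgd1 did not pass without dwarf 22 months replicates 2 (0.0621), 3 (0.117) or 5 (0.0538) or dwarf 4 months replicates 1 (0.0938) or 2 (0.0861). Pparg did not pass without dwarf 22 months replicate 3 (0.0618), nor Lcn2 without replicate 4 (0.0546). Of the rises in wild type and in dwarf 12 genes were shared, where independence would give 1.67, and of the falls 21, against 2.02. Both changes used the same variance for each gene, which can raise sharing above independence.

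The respiratory chain list moved toward lower values with age in dwarf too. Oxidative phosphorylation genes had a median of -0.36 (camera adjusted p = 6.06e-29, and 0.0989 with an estimated correlation), with Ndufa5 (-0.61), Cox5b (-0.54), Cox7a2 (-0.51), Cyc1 (-0.48) and Atp5d (-0.46) among 11 of 38 lower (29 adjusted over the list alone). With quantile normalization the medians were -0.18 for this list, -0.17 for ribosomal protein genes and -0.12 for fatty acid oxidation. Cytosolic ribosomal protein genes had a median of -0.32 (5.09e-11, and 0.226 with an estimated correlation), with Rpsa (-0.59), Rps3 (-0.51), Rpl19 (-0.47) and Rps2 (-0.40) lower, 4 of 17 and 8 adjusted over the list alone. Fatty acid oxidation genes had a median of -0.20 (1.61e-06, and 0.351 with an estimated correlation), with Acaa1b (-0.88) and Acaa2 (-0.39) lower, 2 of 24 and 4 adjusted over the list alone. Hepatocyte markers had a median of -0.30 (7.74e-07, and 0.226 with an estimated correlation), with albumin Alb (-0.50), Apoa2 (-0.48) and transthyretin Ttr (-0.45) lower. With quantile normalization the shift of their median vanished, and camera gave the opposite direction without passing (adjusted p = 0.777). Adjusted over the list alone 8 hepatocyte genes were lower and 1 higher. Antioxidant genes had a median of -0.20 (0.00636, and 0.305 with an estimated correlation), with Sod1 lower (-0.86), 1 of 16 and 2 adjusted over the list alone, and did not pass with quantile normalization (0.382). None of these 5 lists lost its call when any single array was left out.

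The remaining 8 lists in dwarf each lost the call when some single array was left out. Cholesterol synthesis was higher, with Sqle the 1 of 19 past the threshold by both counts (median 0.18, adjusted p = 0.00901, and 0.565 with an estimated correlation). It did not pass without dwarf 22 months replicate 2 (0.0599) or dwarf 4 months replicates 4 (0.237) or 5 (0.104). Interferon-stimulated genes were higher, with Iigp1 the 1 of 15 by both counts (median 0.25, adjusted p = 0.0119, and 0.392 with an estimated correlation), but not without dwarf 22 months replicate 3 (0.291). B cell markers were higher, with Ighm (1.52) the 1 of 11 by both counts (median 0.40, adjusted p = 0.0127, and 0.364 with an estimated correlation), but not without dwarf 22 months replicate 2 (0.215) or dwarf 4 months replicate 5 (0.08). Stellate markers were lower, with Sparc (-0.89) the 1 of 14 past the threshold and 2 adjusted over the list alone (median -0.19, adjusted p = 0.0168, and 0.392 with an estimated correlation), but not without dwarf 22 months replicate 4 (0.0989) or dwarf 4 months replicate 1 (0.0943). Glycolysis was lower, with Pgk1 (-0.43) the 1 of 6 by both counts (median -0.16, adjusted p = 0.0257, and 0.263 with an estimated correlation), but not with quantile normalization (0.562) or without dwarf 22 months replicates 1 (0.0505) or 5 (0.0545) or dwarf 4 months replicate 2 (0.0589).

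The glutathione, endothelial and proliferation lists passed toward lower values in ageing dwarf livers with 0 members past the threshold over all genes by limma. Adjusted over the list alone 4, 1 and 0 were lower. The glutathione list (median -0.21, adjusted p = 0.0119, and 0.392 with an estimated correlation) did not pass with quantile normalization (0.447) or without dwarf 22 months replicate 2 (0.0501). Endothelial markers (median -0.19, adjusted p = 0.0257, and 0.392 with an estimated correlation) did not pass without dwarf 22 months replicates 3 (0.0524) or 4 (0.105) or dwarf 4 months replicates 1 (0.0687), 2 (0.0766) or 3 (0.0559). Proliferation genes (median -0.30, adjusted p = 0.0474, and 0.392 with an estimated correlation) did not pass without dwarf 22 months replicates 2 (0.0764), 3 (0.0842) or 5 (0.0658) or dwarf 4 months replicates 1 (0.3) or 2 (0.164). In all 13 lists passed, 3 higher and 10 lower, or 4 and 6 with quantile normalization, and none passed with an estimated correlation.

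Whether ageing itself differed between the genotypes was tested by the interaction of genotype with the change from 4 to 22 months. Mup10 (3.50), Igfals (1.92), Csad (2.34) and the peptidase gene Mme (2.05) changed more upward in dwarf than in wild type, each with an adjusted p of 0.00504. The airway-type P450 Cyp2f2 (1.05), the secretion gene Cadps2 (1.13), the glycine transporter Slc6a9 (0.97) and the thioredoxin-domain gene Txndc15 (0.82) completed the 8 genes with the smallest adjusted p, all on 5 of 5 arrays. Csad fell in wild type from 8335 ± 2995 (SD, n = 5) to 1889 ± 597 (SD, n = 6) while it stood at 366 ± 131 and 414 ± 73 in dwarf (SD, n = 5 each). Igf1 (1.65, adjusted p = 0.0384), Wfdc21 (4.16, 0.0356), Nat8 (2.91, 0.0155), Nkain4 (3.44, 0.0175), Olfm3 (2.26, 0.0397) and Iigp1 (1.12, 0.0175) also changed more upward in dwarf. Gpr37 (-3.60, adjusted p = 0.00894), Lpl (-2.40, 0.038), Trib3 (-1.87, 0.0307) and the inter-alpha-trypsin inhibitor chain Itih3 (-0.76, 0.0396) changed more downward. No difference in the change was found for Lcn2 (-1.07, adjusted p = 0.659), Sult1e1 (-2.997, 0.064), Tifa (0.07, 0.981) or Mup5 (1.66, 0.161). By limma 60 genes passed, 40 higher and 20 lower, or 39 and 7 with median centring. The test of any change of the dwarf difference over the 3 ages called 26, led by Mup10 (adjusted p = 0.00377), Igfals and Csad (both 0.00458), Mme (0.00679), Cadps2 (0.0125), Txndc15 and Cyp2f2 (both 0.0127) and Slc6a9 (0.0142). A second probe set of Slc6a9 (0.41, adjusted p = 0.628) and of Txndc15 (0.32, adjusted p = 0.914) did not pass, nor did the mean of either gene's probe sets (0.149 and 0.525). Slc6a9 left the 26 without dwarf 22 months replicate 3 (0.0514).

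Both counts depended on single arrays. The 60 genes were 26 without dwarf 22 months replicate 3, 31 without replicate 4, 97 without wild type 22 months replicate 2, 23 without replicate 3, 24 without replicate 5, 29 without dwarf 4 months replicate 4 or 5, 30 without wild type 4 months replicate 1 and 24 without replicate 5. The 26 genes were 9 without dwarf 22 months replicate 3 or 4 and 17 and 11 without dwarf 4 months replicates 1 and 5. Leaving out wild type 22 months replicates 1, 2, 3, 5 and 6 in turn gave 42, 54, 10, 14 and 15. It was 16 without wild type 10 months replicate 4, and 17, 14 and 12 without wild type 4 months replicates 1, 3 and 5.

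With the preset correlation only, 9 lists passed for the interaction, and all 9 had an adjusted p of 0.789 with an estimated correlation. The male-biased list had a median of 0.68 (camera adjusted p = 0.00201) and the ribosomal protein list one of -0.25 (0.00201). No member of either passed over all genes, and 4 male-biased genes were higher and 1 ribosomal gene lower adjusted over the list alone. Thyroid hormone-responsive (0.33, 0.0215), interferon-stimulated (0.40, 0.0211) and proteasome genes (0.15, 0.0417) were relatively higher. Acute phase (-0.36, 0.0211), Kupffer cell (-0.38, 0.018), endothelial (-0.33, 0.0211) and hepatocyte genes (-0.23, 0.0349) were relatively lower. Iigp1 was the 1 interferon-stimulated gene and Itih3 the 1 acute phase gene past the threshold, by both counts. Adjusted over the list alone 2 thyroid hormone-responsive genes were higher, 2 endothelial genes were lower, 1 hepatocyte gene was higher and 1 lower, and 0 Kupffer cell or proteasome genes passed. With quantile normalization the thyroid (0.0942), acute phase (0.233), hepatocyte (0.474) and proteasome lists (0.474) did not pass.

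Of these 9 lists, the ribosomal one alone kept its call whichever single array was left out, and without all 4 high-Xist arrays it did not pass (0.0862). Nor did the male-biased (0.071), Kupffer cell (0.0905), endothelial (0.071) and hepatocyte lists (0.0992) without those 4. The male-biased list did not pass without wild type 22 months replicate 2 (0.25). Kupffer cell genes did not pass without dwarf 22 months replicate 1 (0.0929) or wild type 4 months replicate 2 (0.0764), and interferon-stimulated genes not without dwarf 22 months replicate 3 (0.211) or wild type 4 months replicates 1 (0.0514) or 3 (0.0666). Endothelial genes did not pass without dwarf 22 months replicate 4 (0.0552), and acute phase genes not without dwarf 22 months replicate 1 (0.0929), wild type 22 months replicate 5 (0.103) or wild type 4 months replicate 4 (0.0816). The thyroid list did not pass without dwarf 22 months replicate 4 (0.0674), wild type 22 months replicates 1 (0.0597) or 3 (0.0549) or wild type 4 months replicates 3 (0.0535) or 4 (0.0538). Hepatocyte genes did not pass without dwarf 22 months replicates 1 (0.0929) or 2 (0.0739), dwarf 4 months replicates 2 (0.118) or 4 (0.0727), wild type 22 months replicate 4 (0.0823) or wild type 4 months replicates 4 (0.131) or 5 (0.0794). Proteasome genes did not pass without dwarf 22 months replicates 3 (0.362) or 4 (0.153), dwarf 4 months replicates 1 (0.0989) or 4 (0.103), wild type 22 months replicates 1 (0.112), 3 (0.0762), 5 (0.0594) or 6 (0.155), or wild type 4 months replicates 2 (0.252) or 3 (0.0851).

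**Figure D4:**
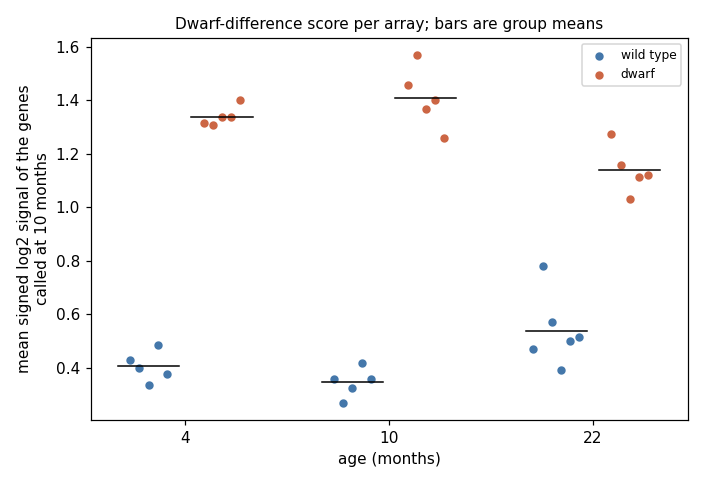
Mean signed log2 level of the 955 genes called at 10 months (y axis), 1 point for each array, by genotype and age in months (x axis), with bars at the group means. The dwarf minus wild type difference was 0.934 at 4 months and 0.6 at 22 months.

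Shorter intervals changed fewer genes. From 10 to 22 months wild-type livers had 70 genes past the threshold by limma, 22 higher and 48 lower (8 and 74 with median centring, which put the median of all genes at -0.11), with Csad lower (-1.90 log2, adjusted p = 0.00236) and Lcn2 higher (2.73, adjusted p = 0.0251). That count was 226, 211, 13, 40, 4 and 34 without wild type 22 months replicates 1 to 6 in turn, and 3, 16 and 21 without wild type 10 months replicates 3, 4 and 5. In dwarf 12 passed, 11 higher and 1 lower, with Wfdc21 (4.18), Mup10 (3.05), Igfals (1.89) and Igf1 (1.65) among the risers. There the count was 34 without dwarf 22 months replicate 1, 6 without replicates 3 or 4, and 7 and 6 without dwarf 10 months replicates 1 and 2. From 4 to 10 months 0 genes passed in wild type by limma, against 1174 at an unadjusted p under 0.05 where chance gives 771, and the smallest adjusted p was 0.0532. In that interval 1 gene passed in dwarf, the splicing-associated Scaf11 (-0.67, adjusted p = 0.0255), which was chosen after its values were seen. Scaf11 did not pass without the 4 high-Xist arrays (-0.69, adjusted p = 0.0643), nor without dwarf 10 months replicate 5 (0.0606) or dwarf 4 months replicates 2 (0.0725) or 4 (0.0924). With quantile normalization 7 genes were higher and 5 lower there. The wild-type count was 1 without wild type 10 months replicate 1 or 2, and 2 and 3 without wild type 4 months replicates 4 and 5. The dwarf count was 2, 4, 3 and 5 without dwarf 10 months replicates 1 to 4, and 3, 0, 0 and 8 without dwarf 4 months replicates 1, 2, 4 and 5.

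The last comparison asked whether genes that change as wild-type livers age already differ in the same direction between dwarf and wild type at 10 months. The 296 risers, such as Lcn2, Sult1e1 and Serpinb1a, had a mean dwarf minus wild type difference of 0.181 log2, and the 318 fallers, such as Csad and Dio1, of -0.177. The difference of 0.358 had an exact two-sided permutation p of 0.00794 over 252 relabelings of the 10 arrays, the smallest possible. The 10-month levels did not enter the difference by which the genes were chosen, but those arrays shared the fit's variance, the filter and the choice of probe sets. A fit of the 4- and 22-month wild types alone called 128 genes, 120 of them among the 614. Of the 614 genes, 70 passed at 10 months in the same direction and 17 in the opposite one. Without the 4 high-Xist arrays the difference was 0.161 (exact p = 0.161), and with only wild type 22 months replicate 2 left out of the choice of genes it was 0.211 (exact p = 0.0317).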

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

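Leaving out the 4 high-Xist arrays was chosen only after the data were seen, for the dwarf difference as well as for the female- and male-biased lists, and for those lists after the test's own result was seen. Keeping the 955 genes below fixed was also chosen after the results were seen. Among 114 checks of 19 measures for an array far from the rest of its group, gaps taken on the log2 scale except for the median signal, 20 stood out, where chance gives about 1 in 20, or 5.7.

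Female-biased genes such as Sult2a2 and Cyp2b13 were higher and male-biased genes such as Hsd3b5 and Slco1a1 lower in dwarf livers, with list medians 4.75 apart. A larger share of female mice among the dwarf arrays would shrink that gap once the 4 high-Xist arrays, 3 of them dwarf, are left out. It stayed at 4.76. The wild-type array among them had high Sult2a2 and low Hsd3b5, so leaving it out widens the gap and can offset a loss. At 4 months, where no array had Xist above 1000, the medians were 2.18 and -3.1. These argue against female mice as the whole explanation. Among members whose probe set is not named as a shared kind, the gap was 4.01. Probe sets of Cyp2b, Sult2a and Mup genes, whose relatives' transcripts probes can share, remained there. That value therefore cannot decide on probes shared between paralogs. The gap goes with genotype, the difference the design names, at 4, 10 and 22 months. The female-biased medians were 2.18, 1.96 and 2.23 and the male-biased ones -3.1, -2.9 and -2.05. Whether something else that differs between the dwarf and wild-type animals adds to the gap was not tested.

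For genes chosen at 10 months, the dwarf difference was smaller at 22 than at 4 months. Over the 955 genes called at 10 months, such as Igf1, Igfals and Mup10, the mean signed difference went from 0.934 to 0.6, a change of -0.334 (exact p = 0.000344). In dwarf it changed by -0.201 (exact p = 0.00794, the smallest possible) and in wild type by 0.133 (exact p = 0.0433), and the wild-type part did not pass without the 4 high-Xist arrays (0.0813, exact p = 0.0714) or with quantile normalization (0.114, exact p = 0.0736). The genes came from a fit to all 6 groups, and the test was not among those fixed before the data were examined. An age of 10 months is nearer to 4 than to 22 months. Over all genes, differences at 10 months correlated at 0.586 with those at 4 months and 0.468 with those at 22 months. The choice can thus favour the 4-month difference, and the settings below keep it. Each exact p of the change shuffled age labels within genotype. It tests for no age change in either genotype, rather than for an equal change in both. With the genes called anew, the change was -0.334 without the 4 high-Xist arrays (671 genes, 1.05 to 0.719, exact p = 0.000283) and -0.287 with quantile normalization (1014 genes, 0.878 to 0.591, exact p = 0.000885). Over the same 955 genes it was -0.319 (exact p = 0.000378) and -0.296 (exact p = 0.00117), which argues against female animals or the signal range of the 22-month arrays as the whole explanation. The age of the animals, and which animals live to 22 months in each genotype, stay open as untested. So does the choice of genes at 10 months, and a weaker dwarf effect in old livers is shown for those genes only.

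Oxidative phosphorylation genes such as Ndufb9, Cyc1 and Atp5d were lower at 22 than at 4 months in both genotypes, by a median of -0.30 in wild type and -0.361 in dwarf, calls that did not hold with an estimated correlation (adjusted p = 0.292 and 0.0989). An intensity-dependent trend would give matched random lists a like median. Of 10000 such lists none was as low, percentile 0 in each genotype, with lowest medians of -0.284 and -0.338 and typical ones of -0.136 and -0.153. These lists do not carry the 0.423 correlation of the list's genes, so they argue against the trend as the whole explanation only as far as lists without it can. With quantile normalization the medians were -0.168 and -0.182, so part of the fall may follow the scaling. Ageing itself stays open as untested. No difference in the change between genotypes was detected (camera adjusted p = 0.473), and the median of that difference changed sign with median centring (-0.0644 to 0.0487).

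Of 100 splits of the arrays, 1 (the real one) gave as many genes for dwarf against wild type at 4 months (1538, highest other 184), 10 months (955, 109), 22 months (635, 360) and over all ages (2945, 221). A random split of the arrays thus rarely gives such counts. The real split was also the only one to reach its count for 22 against 10 months (12, 8) and 22 against 4 months in dwarf (185, 2), the interaction (60, 10) and the F-test (26, 1). The 12 genes stood little above the highest other count, 8. In wild type 2 of 100 splits, the real one included, reached the real count for 22 against 10 months (70, highest other 272) and for 22 against 4 months (614, 731). That share is low, but another split of the same arrays called more genes than the ages did, so chance is not excluded there. The higher split in each set wild type 22 months replicates 1 and 3 to 6 against the younger arrays plus replicate 2. Of these, replicates 3 to 6 stood apart on the second principal component (-41.3, -33.5, -45.1 and -35.9), where all other arrays lay from -14.7 to 31.8. Replicate 1 was at 2.7 there. Replicate 2 itself did not lie with the younger wild-type arrays, with a first principal component of -1.85 against 18.7 to 31.2. For 10 against 4 months in dwarf chance could not be excluded, with 13 splits as high (1, highest other 6). In wild type the real count was 0, which every split reaches, so the splits cannot decide there (highest other 5).

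Wild type 22 months replicate 2 stood apart from the other arrays of its group. Its signal was 29000 for Sult2a2 (others 20.1 to 62.5), 11.3 for Hsd3b5 (6540 to 15500), 671 for Slco1a1 (6160 to 10000), 447 for Elovl3 (9940 to 15200) and 384 for Per1 (45.9 to 79.2). Its median signal was 170 (214 to 227), with Xist at 8170 (13.9 to 79.8) and Eif2s3y at 5.55 (943 to 1260). Its Igf1 (18770), Igfals (3285), Mup10 (5755) and Dio1 (1042) were far above the dwarf means of that age, 5776, 1302, 485 and 47.1. Its Igfbp1 (8358, others 304 to 1611) and Mt1 (19150, others 479 to 12350) were instead near the dwarf means, 10390 and 20430. Its animal name starts with the letters otherwise used for dwarf animals, and whether its label is right was not tested. Dwarf 22 months replicate 1 had Xist at 8410 (14.1 to 30.5) and Eif2s3y at 21.6 (588 to 915), and dwarf 10 months replicate 4 had Eif2s3y at 44.3 (661 to 1040). Dwarf 4 months replicate 1 had Xist at 132 (6.87 to 10).

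Wild type 4 months replicate 4 had Hsd3b5 at 507 (10700 to 17400) and Slco1a1 at 3750 (9090 to 12800). Wild type 10 months replicate 2 had the acute phase genes Lcn2 at 1650 (283 to 428) and Saa1 at 43600 (1740 to 3140). Dwarf 22 months replicate 4 had Lcn2 at 9000 (2180 to 3270) and Dio1 at 156 (10.9 to 24). Dwarf 4 months replicate 2 had Igfals at 171 (306 to 374), and wild type 22 months replicate 4 had Mup10 at 24600 (5760 to 9600).

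The change from 4 to 22 months differed between genotypes by interaction tests for Mup10 (3.50), Csad (2.34), Mme (2.05), Igfals (1.92), Cadps2 (1.13), Cyp2f2 (1.05), Slc6a9 (0.972) and Txndc15 (0.819). Among lists it differed, with the preset correlation only, for male-biased (0.677), interferon-stimulated (0.395), thyroid hormone-responsive (0.329) and proteasome genes (0.145). It differed downward for Kupffer cell (-0.382), acute phase (-0.363), endothelial (-0.331), ribosomal protein (-0.254) and hepatocyte genes (-0.232).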

How the results depend on the processing

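Chosen only after results were seen were leaving out the 4 high-Xist arrays, its 2 partial forms for the wild-type ageing genes, leaving single arrays out of the choice of those genes, and the clock covariate. Signal over background limits genes near the floor, and 5 or 6 arrays per group limit all counts. With 1 array left out, genes named by rank stayed past the threshold in 1752 cases and not in 32, and under other settings in 1442 and 13, with 0 reversed. Genes named only as list members were not part of this tally. List calls stayed in 810 cases and not in 75, and under other settings in 177 and 110, with 1 reversed in direction but not past the threshold. Over all ages gluconeogenesis did not pass by ranks (0.0896), fatty acid synthesis by fry (0.0731) and stellate markers with the mean of probe sets (0.0551). Counts stayed within 1.5 times under the deposited values unscaled, a pseudocount of 64, robust variances and camera on ranks. Where counts moved the cause was not tested, except that fitting probe sets one by one adds tests and fitting 2 groups uses fewer arrays.

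Quantile normalization gave 12 genes for 10 against 4 months in dwarf, 34 for the interaction, 13 for the F-test, 7 lists in wild type and 5 for the interaction. It removed the median shift of hepatocyte markers in dwarf, where camera turned direction without passing (adjusted p = 0.777). Median centring gave 1150 genes for 22 against 4 months in wild type, 61 in dwarf, 6 for 22 against 10 months and 2 for 10 against 4 months in dwarf. A pseudocount of 1 gave 2 genes for 10 against 4 months in wild type, and no filter 46 for 22 against 10 months in wild type. The 60th percentile filter gave 2 and 11 for 10 against 4 months in wild type and dwarf, and 20 for 22 against 10 months in dwarf. All probe sets one by one gave 2363 at 4 months, 958 at 22 months, 4776 over all ages, 4 and 9 for 10 against 4 months in wild type and dwarf, 28 for 22 against 10 months in dwarf, 1370 and 314 for 22 against 4 months in wild type and dwarf, and 41 for the F-test.

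The mean of probe sets gave 40 genes for 22 against 10 months in wild type, 0 for 10 against 4 months in dwarf (limma), 37 for the interaction and 5 lists in wild type. Array weights gave 1076 at 22 months, 2 and 23 for 10 against 4 months in wild type and dwarf, 261 for 22 against 10 months in wild type, 290 for 22 against 4 months in dwarf and 44 for the F-test. Without the trend there were 28 and 7 for 22 against 10 months in wild type and dwarf, 0 for 10 against 4 months and 119 for 22 against 4 months in dwarf, 22 for the interaction and 9 for the F-test. Fits of only the 2 groups gave 373 at 22 months, 1 and 4 for 10 against 4 months in wild type and dwarf, 16 and 0 for 22 against 10 months, and 128 for 22 against 4 months in wild type. With an estimated correlation 4, 0, 0 and 0 lists passed over all ages, in wild type, in dwarf and for the interaction, and fry called 7, 4 and 0 in the last 3.

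Without the 4 high-Xist arrays there were 187 genes for 22 against 10 months in wild type, 0 for 10 against 4 months in dwarf, 47 for the F-test and 4 interaction lists, and the wild-type ageing genes differed by 0.161 at 10 months (exact p = 0.161). The clock covariate gave 8 for 22 against 10 months in wild type.

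Leaving out 1 array at a time gave 1319 to 1510 genes at 4 months, 690 to 927 at 10 months, 376 to 1041 at 22 months and 2776 to 3133 over all ages. It gave 0 to 3, 3 to 226 and 246 to 900 for 10 against 4, 22 against 10 and 22 against 4 months in wild type, and 0 to 8, 6 to 34 and 66 to 187 in dwarf. The interaction had 23 to 97, the F-test 9 to 54, and the lists 13 to 15, 7 to 15, 9 to 15 and 6 to 10. The ageing genes differed by 0.324 to 0.407 with 1 array of 10 months left out, and by 0.211 to 0.476 with 1 wild-type array of 4 or 22 months left out of the choice of genes, lowest without wild type 22 months replicate 2.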

Other observations

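The settings without high-Xist arrays were chosen only after the results were seen. Single genes of lists that did not pass over all ages also differed between dwarf and wild type. The clock gene Per1 was higher (2.18, adjusted p = 6.85e-07), as were Tef (0.68), Cry2 (0.50) and Per3 (0.48), while Nfil3 was lower (-0.56), with the clock list not past the threshold (camera adjusted p = 0.366). The metallothioneins Mt1 (3.64) and Mt2 (3.26) and the plasma peroxidase Gpx3 (0.996) rose in an antioxidant list that did not pass (0.121). Among fatty acid oxidation genes Cyp4a14 (5.87), Ehhadh (0.81), Acadl (0.59) and Acadm (0.46) rose and the hormone gene Fgf21 fell (-1.70, adjusted p = 0.000473), in a list that did not pass (0.238) and whose median, 0.02, changed sign with quantile normalization. The insulin receptor substrates Irs2 (1.09, adjusted p = 0.00592) and Irs1 (0.49) and the receptor Insr (0.35) rose and Pik3r1 fell (-0.62), in a list at 0.61. The stress genes Gadd45b (1.40) and Gadd45g (-1.66) went apart, and the chaperone genes Hspb1 (-0.93) and Bag3 (-0.76) fell, in lists at 0.388 and 0.207. The heme synthesis gene Alas2 (-1.57) and the elastase Cela1 (-1.35) fell, in lists at 0.65 and 0.366.

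Dwarf 10 months replicate 1 had both a high Xist signal, 5582, and Y-linked signals, with 707.8 for Eif2s3y, 275.4 for Uty and 303.2 for Kdm5d. Uty ran from 234.6 to 441 on the arrays with low Xist. The genes that change in ageing wild types differed at 10 months by 0.32 (exact p = 0.0179) with the high-Xist arrays left out of that difference alone.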
